A study of Mus musculus with 8 samples.

How the data were processed

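RNA from morula and blastocyst pools of mouse embryos was measured as gene-level expression in 8 libraries, 2 for each of NC and KD at each stage. Per the labels' protocols, RNA was extracted with a PicoPure kit from 20 embryos per pool, polyadenylated RNA was taken on oligo(dT) beads, and libraries were made with a NEBNext Ultra kit, 12 to 15 PCR cycles and paired-end reads of 150 bases. The series names embryonic days 3.75 and 4.25 without saying which stage was taken on which day, and neither how the knockdown was done nor what NC stands for is given in the sources used here. Groups were taken from the sample titles. Nothing in the labels says that libraries of a group came from separate litters or days, so p-values measure only the spread between these libraries, which may be technical.

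The values the authors deposited are a normalized signal per gene, called normalized abundance in the report, in 1 table for each stage. Per the submitters' processing notes, Salmon 0.14.1 and DESeq2 were used with the mm10 genome build, and the role of each tool is not given in the sources used here. The 4 columns of a table have nearly equal sums, 17151880 to 17823304 in morulae and 18896774 to 19247880 in blastocysts, so the values were scaled within a table and not between tables. Levels of different tables are therefore not compared by a test of single genes. The closing section uses the difference of levels between the tables only in rank correlations across genes. Values of genes found in a single library lay on whole multiples of 1 step per library in 95.0% to 100% of cases (tolerance 0.01), and the column sum divided by that step gave the estimated depths. They were 18568756 and 17229323 reads in NC morulae, 17856823 and 16177240 in KD morulae, 13958296 and 23304923 in NC blastocysts and 22030598 and 18486998 in KD blastocysts. Low values of genes found in several libraries were whole in 21.6% and 20.3% of cases, so whole reads were not recovered and no count test was run. Depth therefore sets no interval for single values, and the spread between libraries is the error given throughout.

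Genes are identified by Ensembl IDs, of which 98.9% in each table matched a symbol in the gene name table used, and coordinates come from GENCODE vM21 on mm10. The mean over the 4 libraries of a table had to reach 10, which left 13404 genes in morulae and 13651 in blastocysts, 12875 of them in both. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), KD minus NC in each table, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this log2(value + 1) scale, which understates changes of low genes. With 2 libraries against 2, a permutation test could not reach 0.05, so none is given for single genes. The difference between stages was tested in 1 limma fit of all 8 libraries as the KD change in blastocysts minus that in morulae. Values per group are means ± SD.

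In total 28 gene lists were fixed before the data were examined. They are ISWI complex partners, other chromatin remodelers, DNA methylation machinery, epiblast and pluripotency, primitive endoderm, trophectoderm, cavity formation and epithelial junctions, Hippo pathway and its targets, FGF and MAPK signalling, two-cell-stage genes, oocyte and maternal transcripts, p53 targets and apoptosis, DNA replication and S phase, mitosis, replication-dependent histones, ribosomal proteins, ribosome biogenesis, glycolysis, nuclear genes of oxidative phosphorylation, the mitochondrial genome, cholesterol synthesis and uptake, unfolded protein and integrated stress response, heat shock, interferon response, imprinted genes, cumulus with granulosa and stromal cell markers, blood cell markers, and oviduct and uterine epithelium markers. Lists with at least 5 tested members, 26 in morulae and 27 in blastocysts, were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a stage. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. No list call held with an estimated correlation, and fry called none at either stage.

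The genes named were set by a rule written before the data were examined. It takes Smarca5 and its ISWI partners, 14 fixed lineage and cell cycle markers, the 10 largest called changes in each direction whose KD libraries lie on one side of NC, and, where fewer pass, up to 5 more by p, said not to pass. It also takes up to 4 members per list and stage with the smallest p. Genes with no symbol, clone names and pseudogenes were left out of the ranking. Lamb1, Btg2, Mbd1 and Dnmt3l were named outside the rule, after their values were seen, to complete a count of 5 or fewer, as were the genes of the mean change over both stages in the closing section.

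The fit was tested on simulated data with the real means and 200 changed genes. The spread was the observed variance smoothed over genes of like mean, and libraries were drawn independently. Differences in spread between such genes and effects shared by libraries were thus left out, so recovery in the real data may be lower. For morulae, with 13404 simulated genes, the fit recovered 46%, 66%, 82% and 98% of genes changed by log2 folds of 1, 2, 3 and 4, with 25 false calls among 171. For blastocysts, with 13651 genes, it recovered 60%, 76%, 84% and 96%, with 6 false calls among 164. For the difference between stages it recovered 83.8% of 191 genes whose simulated log2 fold differed by at least 3, with 16 false calls among 264. Alternatives, chosen before the data were examined unless the closing section says otherwise, were pseudocounts of 0.1 and 10, no filter and a minimum mean of 100, median-of-ratios and quantile scaling, a fit with the replicate number as a block, a fit without the trend, all 8 libraries in 1 fit, an adjusted p under 0.1, an absolute log2 fold change of at least 1, and leaving out each library in turn. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.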

Results

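Polyadenylated RNA was sequenced from pools of mouse preimplantation embryos with knockdown (KD) of Smarca5, also known as Snf2h, and from a control group labelled NC. SMARCA5 is an ATPase of the ISWI family, which slides and spaces nucleosomes along DNA. Embryos were collected as morulae, the compacted stage before a cavity forms, and as blastocysts, which have an inner cell mass, an outer trophectoderm and a fluid-filled cavity. Each stage had 2 NC and 2 KD libraries, 8 in all, and each library came from 20 embryos. The tables listed 19485 genes for morulae and 20348 for blastocysts. The depth behind them, estimated from the step between low values, was 16177240 to 18568756 reads per library in morulae and 13958296 to 23304923 in blastocysts.

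The targeted gene was examined first, in every library. Smarca5 (ENSMUSG00000031715; mm10 chromosome 8, 80698507 to 80739497, minus strand, a protein-coding gene) fell 20.0-fold in KD morulae. Its normalized abundance was 9678 and 9760 in the NC libraries against 501 and 470 in the KD libraries, or 9719 ± 58.5 (SD, n = 2) against 486 ± 21.4 (log2 fold change -4.32, SE 0.13, limma adjusted p = 1.88e-04). In KD blastocysts Smarca5 fell 8.65-fold, from 7000 and 8283 in NC to 906 and 855 in KD, or 7641 ± 907 against 880 ± 36.0 (SD, n = 2; log2 fold change -3.11, SE 0.12, adjusted p = 5.93e-04). The log2 fold change was 1.21 higher in blastocysts than in morulae, which did not pass the test of the difference (adjusted p = 0.206). Without the mean-variance trend in limma the adjusted p became 0.111 in morulae and 0.103 in blastocysts.

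**Figure D1:**
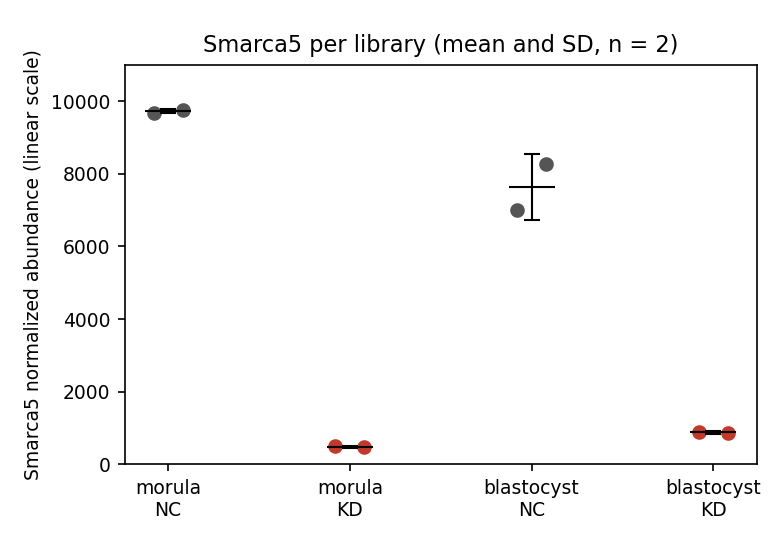
Normalized abundance of Smarca5 (y axis, linear scale) in each NC and KD library (points) at both stages (x axis), with the mean and SD over 2 libraries as bars. The KD libraries lie between 470 and 906 and the NC libraries between 7000 and 9760.

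Of 13 tested partners of SMARCA5 in the ISWI complexes, none passed at either stage, over all genes or adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.795 in morulae and 0.973 in blastocysts). Both KD libraries lay below both NC libraries for 6 partners in morulae and above for 0, and in blastocysts below for 3 and above for 2. The test recovered 46% of simulated 2-fold changes in morulae and 60% in blastocysts, so changes of this size were often missed in simulation. The simulation left out differences in spread between genes of like mean, so recovery in the real libraries was not measured. In the real morulae 895 genes differed at least 2-fold without overlap of KD and NC libraries, and 1 gene passed. The simulated rates may therefore not hold there. Bptf, the large subunit of the NURF complex, was 4360 and 4531 in the NC and 5377 and 5302 in the KD libraries of blastocysts (log2 fold change 0.26, adjusted p = 0.188). Pole3 was 1267 ± 192 in NC and 1047 ± 83.3 in KD morulae (SD, n = 2; log2 fold change -0.27, adjusted p = 0.639). The 24 other chromatin remodelers were not called either (adjusted p = 0.824 and 0.558). Among them, Smarca2 was 800 ± 1.86 in NC and 579 ± 1.12 in KD blastocysts (log2 fold change -0.47, adjusted p = 0.164), and Atrx had a log2 fold change of -0.45 (adjusted p = 0.165).

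KD and NC morulae were compared gene by gene, without the replicate number in the fit. A fit with it as a block called many more genes, as the closing section gives. The labels do not say that this number pairs libraries. In the main fit Smarca5 was the only one of 13404 tested genes that fell, and none rose, at an adjusted p under 0.05 in limma. At an unadjusted p under 0.05, 691 genes were higher and 700 lower, 1391 in all against 670 expected by chance. The genes next in order did not pass (adjusted p = 0.303). Serpinh1, a collagen chaperone, was 47.6 ± 14.1 in NC and 339 ± 4.16 in KD libraries (SD, n = 2; log2 fold change 2.84, SE 0.33), and Lgals9, a galectin, was 278 ± 29.9 and 847 ± 9.04 (1.61, SE 0.19). Also higher were Arhgap45 (2.26), Stx2 (2.16) and Fscn1, an actin-bundling protein (1561 ± 57.6 and 3125 ± 311). Lower were Nup210, a nuclear pore component (-1.81), Gng12, a G protein gamma subunit (-1.77), Aes, a Groucho-family corepressor (-1.52), Tmem248 (-1.25) and Clint1 (-1.20). KD and NC libraries did not overlap for 41.9% of the tested genes, against 33.3% by chance. Of these genes 895 differed at least 2-fold, 542 higher and 353 lower in KD.

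Markers of early lineages were a fixed set of genes. Pou5f1, the pluripotency factor OCT4, was 26010 ± 1466 in NC and 26360 ± 960 in KD morulae (SD, n = 2; log2 fold change 0.02), and Nanog had a log2 fold change of -0.02, which was 0.0108 after quantile normalization. Sox2 (-0.04), Cdx2 (0.10), Gata3 (0.41), Eomes (-0.38), Gata6 (0.13) and Cdkn1a, a cell cycle inhibitor (-0.34), likewise did not pass. The trophectoderm keratins Krt8 (-0.36, adjusted p = 0.436) and Krt18 (-0.43, adjusted p = 0.377) were lower in both KD morula libraries. Of the 23 tested epiblast and pluripotency genes none passed over all genes. Adjusted over the list alone, Klf4 fell, from 2163 ± 291 to 896 ± 172 (-1.28, adjusted p = 0.305 over all genes), and L1td1, an RNA-binding protein, rose (0.99, adjusted p = 0.362 over all genes). The list was not called (camera adjusted p = 0.955).

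In KD morulae the primitive endoderm genes, which mark the layer of the inner cell mass that faces the cavity, were called higher as a list (camera adjusted p = 4.73e-04; adjusted p = 0.988 with an estimated correlation). Of 18 tested members 14 were higher and 4 lower, with a median log2 fold change of 0.27. None passed over all genes, and 5 rose when adjusted over the list alone. They were Serpinh1, Dkk1, a Wnt inhibitor (12.9 ± 7.98 in NC and 107 ± 60.8 in KD), the receptor Pdgfra (452 ± 134 and 994 ± 261), the transcription factor Sox17 (16.1 and 0 in NC, 186 and 72.7 in KD) and the laminin gene Lamb1 (1678 ± 177 and 2781 ± 764). Gata4 was 112 ± 85.0 in NC and 266 ± 120 in KD (log2 fold change 1.41) and did not pass.

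The unfolded protein and integrated stress response list was also called higher in KD morulae (adjusted p = 1.85e-04; adjusted p = 0.988 with an estimated correlation). Of 25 tested members 21 were higher, with a median log2 fold change of 0.28, and none passed alone or over all genes. The endoplasmic reticulum chaperone Hspa5 was 13085 ± 407 in NC and 18086 ± 1021 in KD (SD, n = 2; 0.47, adjusted p = 0.362), Herpud1 was 93.6 ± 0.705 and 198 ± 17.7 (1.07) and Sdf2l1 had a log2 fold change of 0.69. Ribosomal protein genes were called higher by a small amount (85 tested, 64 higher, median 0.10, adjusted p = 8.95e-04; adjusted p = 0.988 with an estimated correlation), and none passed alone or over all genes. Rpl10 was 5900 ± 436 in NC and 7552 ± 32.5 in KD (0.36). Glycolysis genes were called higher (22 tested, 16 higher, median 0.19, adjusted p = 0.0390; adjusted p = 0.988 with an estimated correlation). Adjusted over the list alone, Gapdh (6448 ± 436 to 9558 ± 290) and Pgk1 (682 ± 98.2 to 1177 ± 88.1) rose, and neither passed over all genes (adjusted p = 0.362).

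Markers of cumulus, granulosa and stromal cells moved with these 4 lists in morulae. All 5 tested members were higher in KD, with a median log2 fold change of 1.30 (adjusted p = 0.0390; adjusted p = 0.988 with an estimated correlation). None passed over all genes or over the list alone. Foxl2, a granulosa cell factor, was 33.9 ± 7.07 in NC and 92.9 ± 22.3 in KD (SD, n = 2), and Inhbb was 87.7 ± 93.8 and 146 ± 36.2. The median of the 5 is the value of Inhbb, which was -0.10 without NC replicate 1, where the list median was 0.24.

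Leaving out 1 morula library leaves an arm of 1, assumed to vary like the other arm, so these fits have less power. The called lists were picked from the same libraries that these fits reuse, which favours a kept direction. The median of each of the 5 called lists kept its direction in all 4 such fits, at 0.24 to 0.39 for primitive endoderm, 0.12 to 0.42 for the unfolded protein list, 0.04 to 0.16 for ribosomal proteins, 0.12 to 0.25 for glycolysis and 0.24 to 1.21 for the cumulus markers. Primitive endoderm passed in each. Without NC replicate 1 the adjusted p was 0.0939 for the unfolded protein list, 0.127 for ribosomal proteins, 0.125 for glycolysis and 0.127 for the cumulus markers, without KD replicate 1 it was 0.734 for ribosomal proteins, and without KD replicate 2 it was 0.444 for glycolysis and 0.204 for the cumulus markers.

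Most gene lists were not called in morulae. The other 21 had camera adjusted p between 0.239 and 0.955, the lowest for p53 targets and apoptosis genes (29 tested, 18 higher). Adjusted over that list alone, Ccng1, a cyclin induced by p53, fell from 3850 ± 303 to 2040 ± 89.8 (SD, n = 2), Zmat3 fell (log2 fold change -0.69) and the apoptosis effector Bak1 rose (1.22). Among 28 genes of cavity formation and epithelial junctions (adjusted p = 0.395; median -0.10, mean 0.03), the desmosome genes Dsp (-0.60) and Pkp2 (-0.72) and the water channel Aqp3 (-0.93) were lower without passing. Adjusted p was 0.394 for interferon response, 0.481 for ribosome biogenesis, 0.631 for mitosis, 0.665 for histones, 0.680 for cholesterol and 0.757 for mitochondrial genes. It was 0.795 for trophectoderm and for oocyte transcripts and 0.805 for the Hippo list. DNA methylation (median 0.03, mean -0.03, tested as higher), FGF and MAPK (-0.01 and 0.01, tested as lower), imprinted genes (0.04 and 0.04, tested as lower), nuclear oxidative phosphorylation genes, two-cell-stage genes, DNA replication and heat shock had an adjusted p of 0.955.

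The blastocyst fit also left out the replicate number, and a fit with it as a block called many more genes. Without the block, in KD blastocysts 5 genes rose and 7 fell among 13651 tested at an adjusted p under 0.05. The largest rises were in Gdpd1, a glycerophosphodiester phosphodiesterase, from 46.0 and 49.4 to 317 and 359 (6.95-fold, adjusted p = 0.0405), and in Smyd1, a muscle-enriched SET-domain methyltransferase, from 210 ± 25.3 to 1274 ± 144 (SD, n = 2; 6.04-fold, adjusted p = 0.0142). Lgals9 rose 2.95-fold (adjusted p = 0.0405), Bak1 2.78-fold, from 286 and 267 to 756 and 785 (adjusted p = 0.0479), and Oxct1, an enzyme of ketone body use, 2.69-fold, from 1085 ± 83.8 to 2923 ± 238 (adjusted p = 0.0380). Id3, an inhibitor of bHLH factors and a BMP target, fell 4.43-fold, from 622 ± 114 to 139 ± 21.7 (adjusted p = 0.0479). Gng12 fell 3.27-fold, Aes 3.21-fold (both adjusted p = 0.0405), Map1s, a microtubule-associated protein, 2.78-fold (adjusted p = 0.0479) and Chga, a secretory granule protein, 2.63-fold (adjusted p = 0.0410). The homeobox gene Cphx3 was 195 and 123 in NC and listed at 0 in both KD libraries (adjusted p = 0.0405). It has near-identical copies among which reads could be split, so its value is uncertain.

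In mm10 these are protein-coding genes. The genes that rose lie on chromosome 11 (Gdpd1, ENSMUSG00000061666, 87033867 to 87074062; Lgals9, ENSMUSG00000001123, 78962974 to 78984946), chromosome 6 (Smyd1, ENSMUSG00000055027, 71213940 to 71322233), chromosome 17 (Bak1, ENSMUSG00000057789, 27019810 to 27029009) and chromosome 15 (Oxct1, ENSMUSG00000022186, 4026383 to 4155344). Besides Smarca5, those that fell lie on chromosome 4 (Id3, ENSMUSG00000007872, 136143497 to 136145755), chromosome 6 (Gng12, ENSMUSG00000036402, 66896397 to 67021350), chromosome 10 (Aes, ENSMUSG00000054452, 81559488 to 81566362), chromosome 8 (Map1s, ENSMUSG00000019261, 70905932 to 70917529), chromosome 12 (Chga, ENSMUSG00000021194, 102554969 to 102565028) and chromosome 14 (Cphx3, ENSMUSG00000094817, 26082297 to 26235744).

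The next blastocyst genes had an adjusted p of 0.0561. Gpx3, a secreted glutathione peroxidase (3.62-fold), Fstl3, an activin antagonist (2.50-fold), Ybx2 (2.14-fold) and Rnf7 (1.58-fold) were higher, and Cphx1 was listed at 0 in NC and at 97.8 and 63.2 in KD. Exosc6, a subunit of the RNA exosome, was 249 ± 74.6 in NC and 18.7 ± 7.12 in KD (SD, n = 2). Also lower were Sfxn1, a mitochondrial serine transporter (2.70-fold), Ddx19a (2.13-fold), Fmnl3 (1.95-fold) and Hsph1, a heat shock chaperone (1.67-fold). At an adjusted p under 0.1 the test called 221 genes, 108 higher and 113 lower, and at an unadjusted p under 0.05 it took 2398 against 683 expected by chance. KD and NC libraries did not overlap for 49.5% of genes against 33.3% by chance, and 1102 of these differed at least 2-fold (637 higher, 465 lower). With 1 library left out, an arm of 1 library is assumed to vary like the other, and the folds of the 12 genes kept their direction at 91.2% to 109% of their size on the log2 scale. That range was narrow by selection, since calling favours genes with little spread within an arm. In these smaller fits Smarca5 passed each time, Smyd1 passed without NC replicate 2 (adjusted p = 0.0489) but not without NC replicate 1 (0.0623), KD replicate 1 (0.146) or KD replicate 2 (0.126), and the other 10 did not pass (lowest adjusted p = 0.0924), among them Oxct1 (1.35 to 1.51), Bak1 (1.43 to 1.53), Gng12 (-1.81 to -1.61) and Chga (-1.44 to -1.35).

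Among the fixed lineage markers in blastocysts, Pou5f1 (log2 fold change -0.12), Nanog (-0.01), Klf4 (-0.40), Gata6 (-0.15), Sox17 (0.42), Pdgfra (0.12), Eomes (0.35) and Cdkn1a (0.04) did not pass. Sox2 was 1925 ± 409 in NC and 1361 ± 134 in KD (SD, n = 2; -0.49, adjusted p = 0.213). Cdx2, the trophectoderm factor, was 9885 ± 328 and 11372 ± 493 (0.20, adjusted p = 0.265). Of 24 epiblast and pluripotency genes none passed over all genes and the list was not called (adjusted p = 0.171). Adjusted over the list alone, L1td1 rose (0.57) and the epiblast chromatin factor Utf1 fell (-0.56).

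Primitive endoderm genes were called higher in KD blastocysts too (camera adjusted p = 5.06e-05; adjusted p = 0.618 with an estimated correlation). Of 23 tested members 20 were higher, with a median log2 fold change of 0.46. None passed over all genes, and 2 rose when adjusted over the list alone, Serpinh1 (1061 ± 359 to 2450 ± 428) and Amn, an endocytic receptor subunit (70.3 ± 34.6 to 258 ± 27.8; SD, n = 2). Gata4 (1.19) and Dkk1 (1.42) were higher without passing. Trophectoderm genes were called higher by a smaller amount (26 tested, 19 higher, median 0.23, adjusted p = 0.0236; adjusted p = 0.642 with an estimated correlation), and none passed alone or over all genes. In that list Hand1 was 253 ± 98.0 in NC and 771 ± 341 in KD, Gata3 was 8407 ± 541 and 10538 ± 193, Krt8 had a log2 fold change of 0.25 and Krt18 of 0.29.

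The unfolded protein and integrated stress response list was called higher in KD blastocysts (adjusted p = 5.06e-05; adjusted p = 0.618 with an estimated correlation). Of 25 tested members 23 were higher, with a median of 0.33. None passed over all genes, and adjusted over the list alone 6 rose and 1 fell. Psat1, a serine synthesis enzyme, rose from 3898 ± 68.0 to 6199 ± 435 (SD, n = 2), the endoplasmic reticulum chaperones Hspa5 and Hyou1 rose by log2 fold changes of 0.48 and 0.50, and Shmt2, a mitochondrial enzyme of serine use, fell from 1275 ± 113 to 708 ± 36.9. Cholesterol synthesis and uptake genes were called higher (24 tested, 20 higher, median 0.21, adjusted p = 0.00607; adjusted p = 0.618 with an estimated correlation), and none passed alone or over all genes. Among them Fdps (0.37), Mvd (0.57) and Msmo1 (0.45) were higher and Sc5d (-1.25) was lower.

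Several lists of growth and cell division genes were called in KD blastocysts, in both directions. Ribosome biogenesis genes were called lower (43 tested, 35 lower, median -0.12, adjusted p = 7.00e-04; adjusted p = 0.618 with an estimated correlation). None passed over all genes, and adjusted over the list alone Ncl, the gene of nucleolin, fell from 22693 ± 337 to 16524 ± 155 (SD, n = 2). DNA replication genes were called lower (41 tested, 28 lower, median -0.11, adjusted p = 0.0359; adjusted p = 0.618 with an estimated correlation), and of these the helicase subunit Mcm3 fell from 3395 ± 162 to 2219 ± 86.1 adjusted over the list alone, with none over all genes. Nuclear genes of oxidative phosphorylation were called lower (79 tested, 58 lower, median -0.08, adjusted p = 0.0284; adjusted p = 0.722 with an estimated correlation), with no member past the threshold alone or over all genes. Mitosis genes were called higher (36 tested, 27 higher, median 0.10, adjusted p = 0.0284; adjusted p = 0.722 with an estimated correlation), among them Ube2c (0.40) and Aurka (0.34), and none passed alone or over all genes.

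Replication-dependent histone genes were called higher in KD blastocysts (37 tested, 29 higher, median 0.43, adjusted p = 0.0284; adjusted p = 0.642 with an estimated correlation), with no member past the threshold alone or over all genes. Most histone messages of this kind lack a poly(A) tail, and Hist1h4i was 130 and 87.2 in NC and 196 and 206 in KD. All 13 genes of the mitochondrial genome were higher (median 0.12, adjusted p = 0.0188; adjusted p = 0.618 with an estimated correlation), though after quantile normalization 8 were higher and 4 lower with an adjusted p of 0.5798. No mitochondrial gene passed alone or over all genes. DNA methylation genes were called lower as a list (15 tested, 11 lower, median -0.18, adjusted p = 0.0446; adjusted p = 0.628 with an estimated correlation), yet members moved both ways. Adjusted over the list alone, the imprint protector Zfp57 (1679 ± 145 to 1025 ± 84.3), Uhrf1, a cofactor of maintenance methylation (6441 ± 172 to 4397 ± 596), Uhrf2 and Mbd1 fell, and the de novo methyltransferase Dnmt3a (2591 ± 306 to 3853 ± 384) and its partner Dnmt3l rose, with none over all genes.

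The lists called in blastocysts were picked from the same libraries that the smaller fits reuse, which favours a kept direction. With 1 blastocyst library left out, and its arm of 1 assumed to vary like the other, the medians of all 11 called lists kept their direction in all 4 fits. They ran from 0.38 to 0.80 for primitive endoderm, 0.07 to 0.38 for trophectoderm, 0.31 to 0.36 for the unfolded protein list, 0.17 to 0.29 for cholesterol, -0.21 to -0.09 for ribosome biogenesis, -0.15 to -0.07 for DNA replication, -0.11 to -0.01 for oxidative phosphorylation, 0.04 to 0.17 for mitosis, 0.17 to 0.65 for histones, 0.09 to 0.15 for the mitochondrial genome and -0.30 to -0.08 for DNA methylation. Primitive endoderm, unfolded protein response and ribosome biogenesis passed in each. Without NC replicate 2 the adjusted p was 0.107 for cholesterol, 0.191 for the mitochondrial genome, 0.148 for DNA replication, 0.111 for oxidative phosphorylation and 0.161 for DNA methylation, and without NC replicate 1 it was 0.155 for trophectoderm, 0.247 for mitosis, 0.280 for histones, 0.0541 for DNA replication, 0.0505 for oxidative phosphorylation and 0.0616 for DNA methylation. Without KD replicate 1 it was 0.0550 for the mitochondrial genome, 0.686 for oxidative phosphorylation and 0.376 for DNA methylation, and without KD replicate 2 it was 0.645 for trophectoderm, 0.841 for mitosis, 0.299 for histones and 0.292 for DNA replication.

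The other 16 lists were not called in blastocysts, with adjusted p between 0.0558 and 0.973, but several held members that passed when adjusted over the list alone. That adjustment does not cover the number of lists. Of all tested blastocyst genes 17.6% had an unadjusted limma p under 0.05, so such members need not be particular to a list. In the Hippo list (19 tested, adjusted p = 0.558; median -0.09, mean 0.11, tested as higher) 4 rose, Amotl1 from 29.3 ± 0.167 to 148 ± 7.57 (SD, n = 2), Lats2, Ajuba and Amotl2. In the p53 and apoptosis list (29 tested, adjusted p = 0.681) Bak1, which also passed over all genes, Trp53inp1 and Btg2 rose and Ccng1 and Rrm2b fell. The claudin gene Cldn3 rose 2.01-fold in the cavity and junction list (28 tested, adjusted p = 0.0773), Hsph1 fell in the heat shock list (adjusted p = 0.937), Bbx rose among imprinted genes (adjusted p = 0.1405), Tcl1 fell among oocyte transcripts (adjusted p = 0.558) and Pecam1 fell among the cumulus, granulosa and stromal markers (adjusted p = 0.678). FGF and MAPK genes (21 tested, 15 lower, adjusted p = 0.0558), with Etv5 at -0.64 and Spry1 at -0.94, glycolysis (adjusted p = 0.0705), interferon (0.113), two-cell-stage (0.536), ribosomal protein (0.937) and blood cell lists (0.741; median -0.24, mean -0.03, tested as higher) had no such member. Oviduct markers at both stages and blood cell markers in morulae had fewer than 5 tested members.

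**Figure D2:**
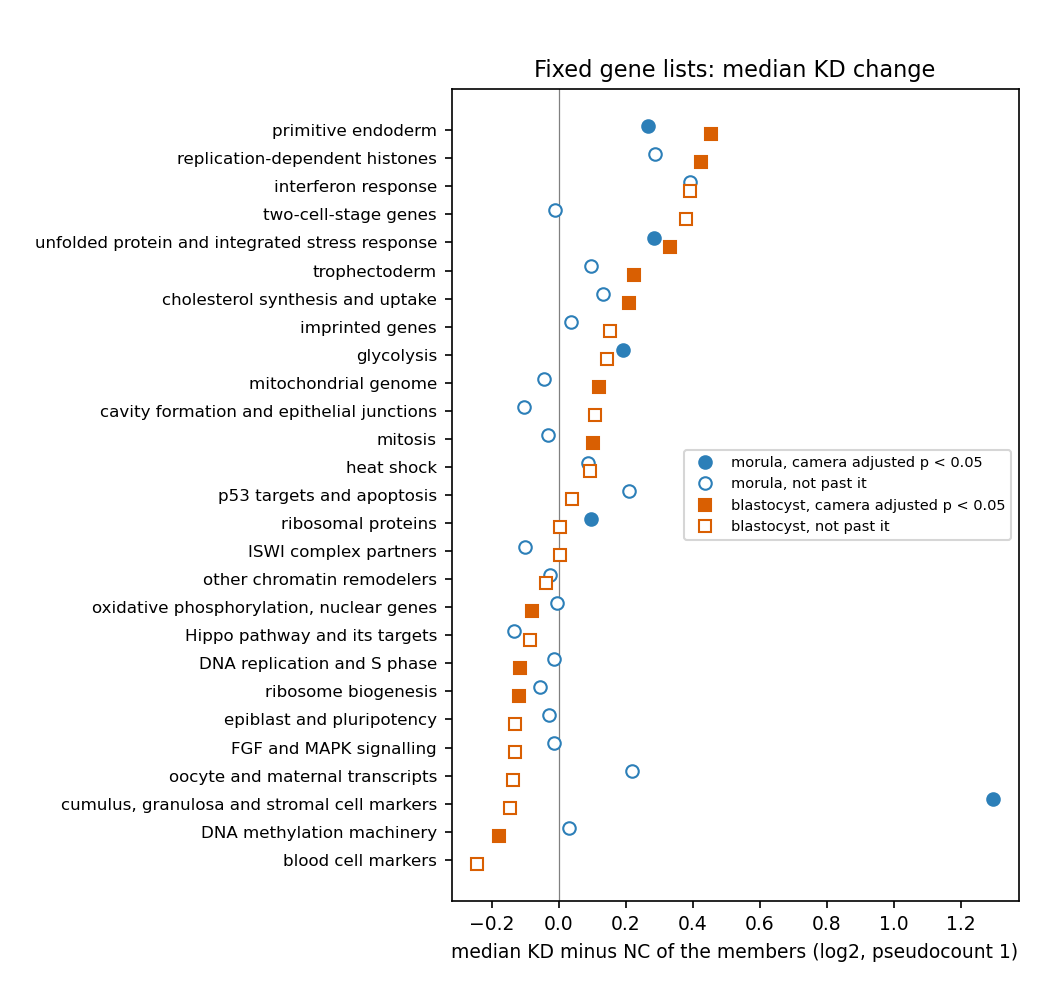
Median KD minus NC change (x axis, log2 with pseudocount 1) of each fixed list (y axis) in morulae (circles) and blastocysts (squares), filled where the camera adjusted p lies under 0.05. Primitive endoderm has medians of 0.27 and 0.46, and the cumulus markers 1.30 in morulae.

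The KD changes of the 2 stages were then set against each other over 12875 genes tested in both. No gene's KD change differed between stages at an adjusted p under 0.05 in limma, and 687 had an unadjusted p under 0.05 against 644 expected by chance. Even Smarca5, with a difference of 1.21 (SE 0.16), did not pass this limma test (adjusted p = 0.206). The absence of calls therefore does not show that the stages responded alike. Across genes, which are not independent replicates, the changes correlated with Pearson r = 0.416 and Spearman rho = 0.411, and 64.5% had the same sign. Smarca5 alone was called at both stages. Of the other 11 genes called in blastocysts, 9 had both KD libraries on the same side of both NC libraries in morulae, among them Gng12, Aes, Chga, Lgals9, Bak1, Oxct1 and Gdpd1, and Id3 and Cphx3 did not. At an unadjusted p under 0.05, 263 genes were higher at both stages against 58.4 expected from independent lists, and 256 were lower at both against 62.0. Opposite changes were found for 8 and 10 genes against 59.8 and 60.6 expected.

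**Figure D3:**
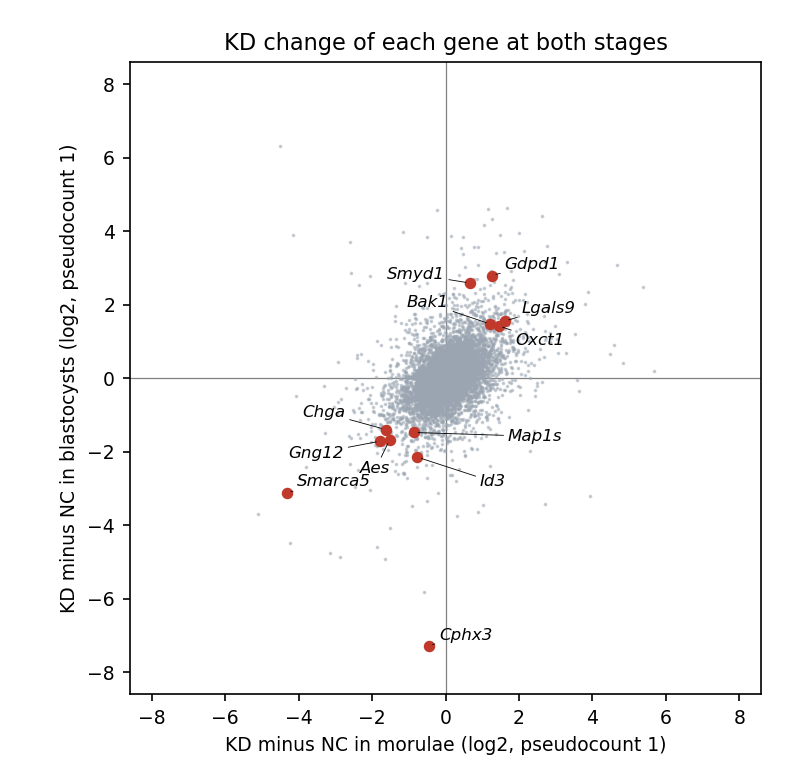
KD minus NC change of 12875 genes in morulae (x axis) and blastocysts (y axis), both as log2 of normalized abundance with pseudocount 1. Red points are the 12 genes called in blastocysts, of which Smarca5 (-4.32 and -3.11) was called at both stages.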

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

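The tests of list differences between stages were not in the written plan, so they are not counted as planned. That plan held list tests within each stage and a test of single genes between stages. Lists were marked for a closer look where their KD change differed between blastocysts and morulae at an adjusted p under 0.05 in camera with the preset correlation. Ribosomal protein genes had a median change of 0.10 in morulae and 0.00 in blastocysts (adjusted p of the difference 0.00166). Mitosis genes moved from -0.03 to 0.10 (0.0165), genes of cavity formation and epithelial junctions from -0.10 to 0.11 (0.0337), genes of the mitochondrial genome from -0.05 to 0.12 (0.0337) and ribosome biogenesis genes from -0.06 to -0.12 (0.0337). Cumulus, granulosa and stromal markers moved from 1.30 to -0.15 (0.0442), and nuclear genes of oxidative phosphorylation from -0.00 to -0.08 (0.0442). With an estimated correlation the adjusted p was 0.792 for ribosome biogenesis and 0.789 for the other lists, and no single gene differed between stages at an adjusted p under 0.05 in limma.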

How the results depend on the processing

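The mean change over both stages and the threshold of unadjusted p under 0.05 for genes called at both stages were chosen only after results were seen, and all other alternatives were planned. Smarca5 kept its log2 fold change of -4.32 in morulae and -3.11 in blastocysts without the trend, with adjusted p of 0.111 and 0.103. Genes called in blastocysts were 12, and 27 without a filter, 0 without the trend, 221 at an adjusted p under 0.1 and 1 to 3 with a library left out. A fit without a library has an arm of 1, assumed to vary like the others. The log2 fold changes of the 12 genes stayed at 91.2% to 109% of their size there. Calling favours genes with little spread within an arm, so this narrow range followed from the selection of the 12. The 1 morula call became 0 without the trend and 18 with all 8 libraries in 1 fit, which holds only genes past the filter in both tables. Genes called at both stages were 1, 0 without the trend, 5 with all libraries in 1 fit and 519 at an unadjusted p under 0.05. Genes differing between stages were 0, 2 with a pseudocount of 0.1 and 0 to 2 with a library left out. Genes with a mean change were 385, 135 without the trend, 1006 at an adjusted p under 0.1, 163 at an absolute log2 fold change of at least 1 and 7 to 299 with a library left out. The labels do not say that replicate numbers pair libraries, and with 2 per group no pairing was set from the data (correlation of replicate deviations 0.297 in morulae and 0.146 in blastocysts). With the replicate block the calls were 892 in morulae, 1208 in blastocysts, 303 at both stages, 1 for the difference and 1543 for the mean change, while on simulated data with no pairing the block moved calls from 171 to 172 in morulae and from 164 to 198 in blastocysts. The 11 blastocyst lists became 6 with quantile normalization, 5 without the trend, 4 with all libraries in 1 fit, 0 with an estimated correlation, 0 with fry and 6 to 11 with a library left out. The 5 morula lists became 2 without the trend, 3 with all libraries in 1 fit, 0 with an estimated correlation, 0 with fry and 4 to 7 with a library left out, and the cumulus markers have too few members at a minimum mean of 100. Without NC replicate 1 the morula calls were 2 higher and 3 lower, the lower ones two-cell-stage (adjusted p = 0.0225), ribosome biogenesis (0.0196) and mitochondrial genome (0.0137), while without NC replicate 2 two-cell-stage genes (0.0393) and p53 targets (5.16e-06) were called higher. Cholesterol was called lower in morulae without KD replicate 1 (0.00206) but higher without NC replicate 1 (5.16e-04) or KD replicate 2 (1.21e-06) and with the block (0.0131). Lists gained in blastocysts were epiblast and pluripotency, lower without NC replicate 1 (0.0143) or KD replicate 2 (0.0415), FGF and MAPK, lower without a filter (0.0205), at a minimum mean of 100 (0.0404) and without KD replicate 2 (0.0319), glycolysis, higher at a minimum mean of 100 (0.0396), with the block (0.0366) and without NC replicate 1 (0.0161) or KD replicate 2 (0.0319), cavity formation, higher without KD replicate 1 (0.0316), and two-cell-stage genes, higher without KD replicate 2 (0.0319). Median-of-ratios scaling moved nothing, which was fixed in advance. Its factors were already nearly equal, 1.00474 to 1.00476 in morulae and 1.00292 to 1.00299 in blastocysts. Quantile normalization turned the median of ribosomal proteins in blastocysts (0.00 to -0.02). In morulae it turned those of other remodelers (-0.03 to 0.01), FGF and MAPK (-0.01 to 0.03), DNA replication (-0.01 to 0.01), mitosis (-0.03 to 0.00) and oxidative phosphorylation (-0.00 to 0.03). It gave Nanog 0.0108 in morulae. With a library left out, log2 fold changes in morulae ran from -0.25 to 0.22 for Nanog, -0.0376 to 0.0775 for Pou5f1, -0.18 to 0.10 for Sox2, -0.28 to 0.47 for Cdx2, -0.99 to 0.23 for Eomes, -1.08 to 0.39 for Cdkn1a and -0.10 to 2.69 for Inhbb. In blastocysts they ran from -0.12 to 0.11 for Nanog, -0.38 to 1.08 for Eomes, -0.11 to 0.19 for Cdkn1a, -0.0213 to 0.27 for Pdgfra and -0.13 to 0.97 for Sox17. A count test with edgeR or DESeq2 was not run, since whole reads were not recovered.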

Other observations

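The mean of the KD changes at both stages, tested in 1 limma fit of all 8 libraries, was chosen only after the stage results were seen, as were the depth and strain tests of the patterns weighed below and the genes named here. By this test 385 of 12875 genes passed at an adjusted p under 0.05, 197 higher and 188 lower. For 378 of them all KD libraries lay on one side of NC at both stages. The test favours genes whose arms are apart in these same libraries, so that count followed largely from the selection. No list of these genes was fixed or tested for enrichment. The BMP ligands Bmp2 (mean log2 fold change 2.81, SE 0.41, adjusted p = 0.0199) and Bmp7 (2.10, SE 0.39, adjusted p = 0.0333), the membrane protease Mmp14 (2.93, SE 0.37, adjusted p = 0.0155), the basement membrane proteoglycan Hspg2 (1.84, adjusted p = 0.0147), Fbln5 (2.13, adjusted p = 0.0199) and Serpinh1 (2.04, SE 0.20, adjusted p = 0.0079) rose, and the laminin gene Lama3 fell (-2.46, SE 0.29, adjusted p = 0.0144). The calcium channel genes Cacna1i (3.25, SE 0.40, adjusted p = 0.0147) and Cacng8 (3.18, adjusted p = 0.0219) and Apoa1 (2.36, adjusted p = 0.0147) also rose, and the exosome gene Exosc6 fell (-4.39, SE 0.75, adjusted p = 0.0264).

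Members of several fixed lists passed in the mean over both stages, and of them only Bak1 (1.35) had passed over all genes at a single stage. Of 25 unfolded protein and integrated stress response genes 4 rose, Hspa5 (0.47), Sdf2l1 (0.52), Xbp1 (0.44) and Psat1 (0.47), and of 18 primitive endoderm genes Serpinh1, Dkk1 (2.19) and Amn (1.42) rose. The glycolysis genes Gapdh (0.56) and Pgk1 (0.61) and the Hippo genes Amotl2 (0.51) and Ajuba (0.47) rose. Klf4 fell (-0.84, adjusted p = 0.0353) and L1td1 rose (0.78) among pluripotency genes, Bak1 rose and Ccng1 fell (-0.76) among p53 targets, and Rfc1 (-0.36) and Mcm3 (-0.45) fell and Rpa1 rose (0.37) among DNA replication genes. Ncl (-0.29, adjusted p = 0.0462), the heat shock gene Hsph1 (-0.51) and the imprinted gene Slc38a4 (-0.49) fell, and Rpl7l1 (0.37) rose. With 1 library left out 7 to 299 genes passed in this test.

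Differences between replicate 1 and replicate 2 correlated between NC and KD morulae (r = 0.297 over 13404 genes, 0.301 over the 13265 with known GC content and length), and splitting the 4 libraries by that number gave 3 calls in morulae and 0 in blastocysts. Removing trends in GC content and transcript length took the 0.301 to 0.297, which excludes this bias as the whole cause. Over 3805 genes with a mean of at least 1000 in morulae r was 0.607, which excludes sampling of low values at different depth. Replicate 2 was shallower in both arms of the morulae (depth ratio 0.906 in KD and 0.928 in NC), so other effects of depth cannot be told apart from the replicate number there. In blastocysts replicate 2 was deeper in NC (23304923 against 13958296 reads) and shallower in KD (18486998 against 22030598). The replicate differences of NC and KD blastocysts correlated with r = 0.146. The morula replicate differences followed the stage difference of the other arm with rho of -0.292 and -0.381, a pattern that pools of different developmental age could give.

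For the KD changes shared by both stages 6 causes were weighed. Over 3501 genes with a mean of at least 1000, r was 0.507, which excludes low-value noise as the whole cause. The share of called genes on the chromosome of Smarca5 was 0.980 times that of tested genes. A knockdown need not change the sequence near Smarca5, so this test may have been bound to come out so. It excludes nothing about strain variants elsewhere. Of called genes 4.94% lay on chromosome X or Y against 3.15% of tested genes. By the limit set beforehand this excludes sex ratio as the whole cause, though effects of sex on genes of other chromosomes were not tested. Xist is not in the tables, so its opposition to Y genes was not tested, and none of 5 Y genes passed (lowest adjusted p = 0.160). No 3' UTR heptamer passed with lower KD values at both stages, or at either stage alone (0 of 16253 tested). Taking for each heptamer the larger p of the stages, the smallest was 0.00140 against a threshold of 3.05e-06. The limit set beforehand would exclude seed matches as the whole cause. The power of this test to find a seed effect was not measured, so seed matches stayed open. Of 9 combinations of library splits only 1, the real split, gave a correlation as large as 0.416, against at most 0.110 in others, but 9 splits are too few for a test under 0.05. The KD change hardly followed the stage difference, with rho of -0.00988 in morulae and -0.0381 in blastocysts. Both values lay between the limits set beforehand, so a small effect of an earlier age of KD pools could not be told apart from none.

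The Cphx1 rise and Cphx3 fall in KD blastocysts could come from reads shared between near-identical copies. The summed Cphx value changed by a log2 fold change of -0.96 (limma p = 0.0363, not a permutation test), between the limits set beforehand, so this stayed open. In morulae Cphx1 was 81.7 and 18.6 in NC and 0 and 2.15 in KD.

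Genes of the mean change were searched for clusters, since neighbours can share regulation. The most called genes in a window of 1500000 bases were 7, once on chromosome 4 (16 tested, all 7 zinc finger genes) and once on chromosome 10 (75 tested), and 1185 of 10000 permutations gave a window with as many (permutation p = 0.119). The share of called genes in a window was not tested.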
